A study of Mus musculus with 2 samples.

How the data were processed

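The data are a table of 2 Affymetrix mouse arrays, 1 for RNA pooled from 5 control mice and 1 for RNA pooled from 5 knockout mice, with 45101 probe sets each. The values deposited by the authors are linear signal intensities per probe set, made with MAS5 per the submitters' processing notes; the MAS5 version and options are not given in the sources used here. MAS5 summarises the probes of a probe set from perfect-match and mismatch pairs and scales each array by 1 factor. In both columns the mean after trimming 2% at each end was 500.00, so the arrays had been scaled to the same target and were used as deposited. The 45101 probe sets are those of the full mouse genome array, whereas the submitters' design text names the smaller A version of that array; the probe annotation used here matches the full array. Crypt RNA was extracted with Trizol, per the labels' protocols.

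Signals ranged from 0.0647 to 52433.6 in the control pool and from 0.0736 to 58616.5 in the knockout pool. The 64 control probe sets were set aside, which left 45037. Of these, 34945 were annotated with 1 gene symbol, 932 with several and 9160 had none here, and only the first kind was used to name genes. Symbols were updated through Entrez identifiers to the RefSeq gene table of GRCm38.p6 for 34741 probe sets and otherwise kept. No coordinates are given because no genome build is named for the array.

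Without detection calls, a floor was set at the 50th percentile of all non-control values of both arrays (92.9). Control and knockout had 22737 (50.5%) and 22300 (49.5%) probe sets at or above it. Lower values were raised to the floor before the log2 ratio, knockout minus control, was taken. A gene above the floor on 1 array therefore has a bound, written as "at least", a gene below it on both was not measured, and values at the floor have no order. A gene's value is that of its brightest probe set by mean log2 signal. In all, 10452 genes were above the floor on both arrays, 429 on the knockout array only, 615 on the control array only and 6697 on neither. Bounds make up 34 of the genes at least 2-fold higher and 48 of those at least 2-fold lower. Probe sets whose identifier ends in _s_at or _x_at can bind transcripts of several related genes, which matters for families such as cytochromes P450, heat shock and immunoglobulin genes.

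Measurement error was estimated from 4582 genes with at least 2 probe sets above the floor on both arrays, as the SD of the difference between the 2 brightest divided by the square root of 2. It was 0.28 (0.22 for 2211 genes whose second probe set was at or above the 75th percentile), and the ratios of such pairs correlated across genes with r = 0.51, genes not being independent replicates. A 2-fold difference is 3.58 of these SDs. Log2 signals of both arrays correlated with r = 0.93 across probe sets. The median log2 ratio of genes above the floor on both arrays was -0.039 and its SD 0.43. The 18 hybridisation control probe sets had a median log2 ratio of 0.027 and none differed by more than 0.086. The ratio of 3' to 5' signal, a sign of RNA integrity, was 1.98 in control and 1.64 in knockout for Actb and 0.785 and 0.742 for Gapdh.

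Each group is 1 array, so no test of genotype was made. The genotype, the Cre transgene, the pool and the array cannot be told apart, since both groups received tamoxifen and only the knockout carried Cre. Genes were counted at 2-fold. Each of 25 gene lists, written from textbook knowledge, was described by the number of members at least 1.5-fold higher or lower, its median log2 ratio, and the central 95% of medians of 10000 random lists of the same size matched on mean signal in 20 bins. This describes these arrays and is no test of genotype. The groups, lists, floor, named-gene rule and main alternatives were fixed before the data were examined. That rule sets which genes may be named, and the text names a part of the list members it allows. Genes outside it are named only where the text says that they were chosen after their values were seen, and they are not among the 268 genes recomputed under the alternatives. The genes it allows are Lpcat3, and the 15 genes with the highest and the 15 with the lowest ratio among genes above the floor on both arrays, at or above the 75th percentile (451) on the brighter one and without a probe set of opposite sign. The rule also takes up to 5 bounds per direction with the brighter array at or above that percentile (4 higher and 2 lower existed), the 3 highest and 3 lowest members of each list, and any member of 7 lists, those of cholesterol, fatty acid, phospholipid, stem cell, Wnt, proliferation and Paneth genes. Where other probe sets of a named gene differ clearly from its brightest one, the main cases are given beside it. A further 7 lists were written after the values were seen and serve the closing section, apart from the 4 lymphocyte lists given beside the immune list. List members not named by a probe set with 1 symbol were not analysed here.

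The alternatives were equal medians of measured genes, quantile normalisation, removal of an intensity trend by lowess (fraction 0.3), a floor at the 30th or 70th percentile, a pseudocount equal to the floor in place of it, the median over a gene's probe sets, leaving out _s_at and _x_at probe sets, and thresholds of 1.5-fold and 3-fold. The procedure was tested on simulated data, a simulated knockout array against a simulated control array. Both were drawn from the control array's values with probe error as the only noise, and the changed genes were taken from genes well above the floor. The rates below therefore leave out differences between mice, pools and arrays. They are not error rates of the 2-fold counts, and the share of changed genes called does not cover dim genes. It called 98% of 100 genes changed by 1.5 on the log2 scale and 100% of 100 changed by 2.5, called 8 of 11034 unchanged genes, and 94% of 200 lists of unchanged genes lay in the central 95%. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.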

Results

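The transcriptome of small-intestinal crypts was compared between mice with floxed Lpcat3 alleles (Lpcat3 F/F, control) and mice that also carried Villin-CreERT2, a tamoxifen-activated Cre recombinase expressed in the intestinal epithelium (knockout). Lpcat3 encodes lysophosphatidylcholine acyltransferase 3, which places polyunsaturated fatty acids into membrane phospholipids. Mice of both genotypes were 8 to 10 weeks old, received 1 mg of tamoxifen per day for 5 days, and crypts were taken 2 weeks later. RNA of 5 mice was pooled per genotype and each pool was read on 1 Affymetrix array of 45101 probe sets, so there were no replicates, no test of genotype was possible and no p-value is given. Median probe-set signal was 95.4 on the control array and 90.5 on the knockout array. Of 18193 genes named by at least 1 probe set, 11496 had a signal above the floor of 92.9 on at least 1 array. The technical error of a log2 ratio, taken from different probe sets of the same gene, had an SD of 0.28 (1.21-fold, 4582 genes). This error leaves out the spread between mice and between pools, and the number of arrays limits the precision of every value below.

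The targeted gene was lower on the array labelled knockout. Lpcat3 had a signal of 4691 in the control pool and 928 in the knockout pool, a log2 ratio of -2.34 (5.06-fold lower). It was read by 1 probe set, whose position relative to the floxed exons is not given in the sources used here.

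The comparison of both pools asks which transcripts of the crypt differ when Lpcat3 is deleted from the epithelium. In the knockout pool 162 genes (1.41% of those measured) were at least 2-fold higher and 267 (2.32%) at least 2-fold lower. Hspa1b, an inducible heat shock protein, was higher by a log2 ratio of 3.59 (signal 387 in control, 4651 in knockout), and its 2 other probe sets gave 3.11 and 3.65. Scd2, a stearoyl-CoA desaturase, was 5.86-fold higher (1761 against 10324; log2 ratio 2.55, and 1.21 by its next probe set), and Scd1 was at least 9.16-fold higher, since its control signal of 87.2 lay below the floor. Mboat1, a lysophospholipid acyltransferase of the same protein family as Lpcat3, was at least 8.91-fold higher, with a control signal of 92.8 at the edge of the floor and a knockout signal of 827. Other genes with the highest ratios were Akr1b8 (2.74), the immunoglobulin segment Igkv8-30 (2.74), Sprr1a (2.67), Rab30 (2.59), S100a6 (2.44), Prss16 (2.36), Jchain (2.33), Gsta3 (2.30), Phlda2 (2.24), H2-Q10 (2.24), Il33 (2.15) and Tubb2a (2.05). Csf1r stood at 2.53 by its brightest probe set, but its other probe sets gave 1.21 and 0.65. Anxa10 was at least 8.08-fold and Tnfrsf12a at least 5.38-fold higher.

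At the other end, Cyp2c29, a cytochrome P450, was 9.80-fold lower in the knockout pool (2744 in control, 280 in knockout). Cyp2b10, another cytochrome P450, was 6.29-fold lower (7909 against 1257), and Ces1d, a carboxylesterase, 6.91-fold lower. Several of the lowest genes are known from T and natural killer lymphocytes: Klrd1 had a log2 ratio of -3.21, Cd3g -3.00, Trgv4 -2.83, Ccl5 -2.52, Gzmb -2.51 and Trgv1 -2.32, and Cd7 was at least 10.3-fold lower. Dnase1 (-2.80), Ceacam10 (-2.53), the fatty acid transporter gene Cd36 (-2.28), the stem cell gene Lgr5 (-2.25) and Slc5a12 (-2.20) were also among the 15 lowest, and the water channel gene Aqp8 was at least 6.60-fold lower. Of 37 genes at least 2-fold higher that had a second probe set above the floor, 32 were higher by that probe set too, and of 73 genes at least 2-fold lower 67 were lower by it. The second probe set reached 1.5-fold in the same direction in only 22 of those 37 and 49 of those 73. Over all 4582 genes with a second probe set above the floor, it was higher in 47.2%.

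**Figure D1:**
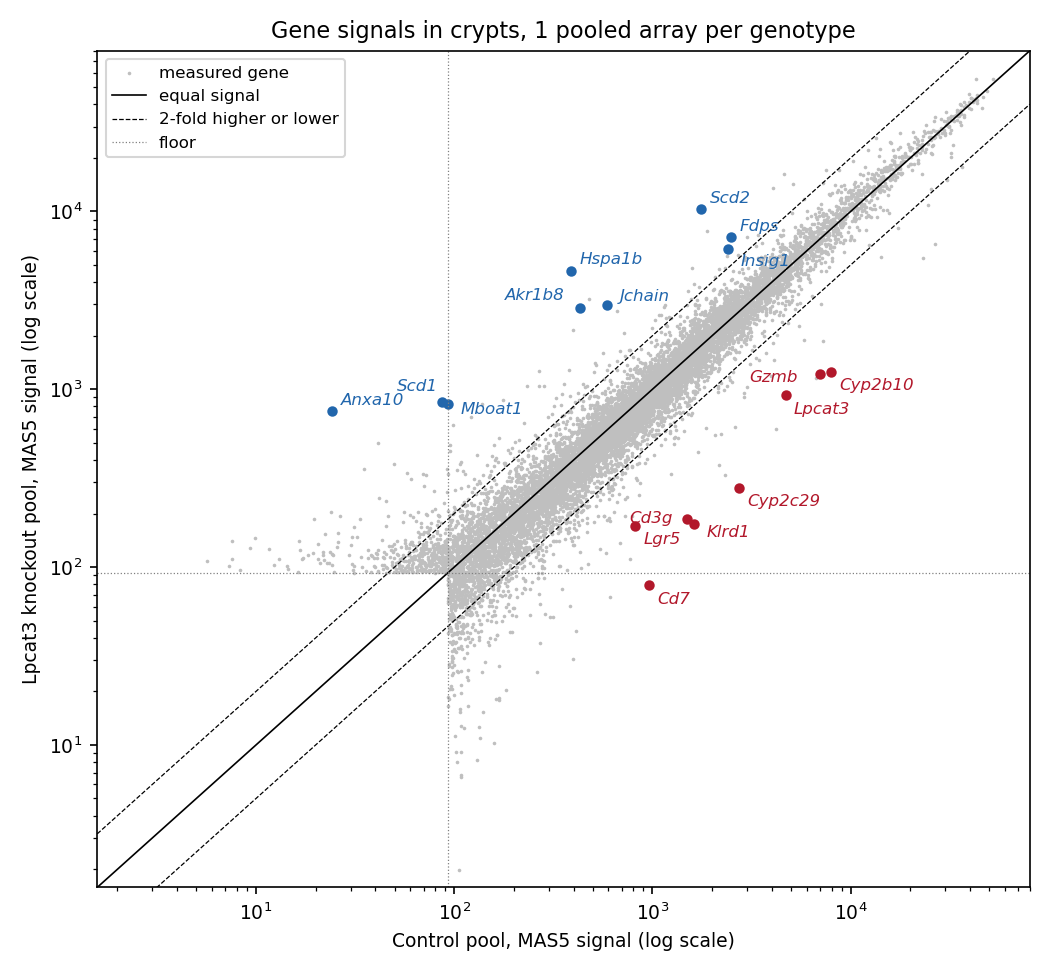
MAS5 signal of each measured gene in the control pool (x axis, log scale) against the Lpcat3 knockout pool (y axis, log scale), 1 array each; grey points are genes, dashed lines mark a 2-fold difference and dotted lines the floor of 92.9. Named genes higher in the knockout pool are blue and those lower are red, with Lpcat3 at 4691 and 928.

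Genes of cholesterol synthesis and uptake were higher together. All 21 measured members were higher in the knockout pool, 18 of them by at least 1.5-fold, and the median log2 ratio was 0.90 (1.86-fold). The medians of the central 95% of 10000 random lists matched on signal lay between -0.15 and 0.15. Lss, lanosterol synthase, had a ratio of 1.75 (381 against 1282), with 0.70 and 1.11 by its other probe sets. Fdps, farnesyl diphosphate synthase, had 1.52 (2493 against 7171), Insig1, a regulator of sterol sensing, 1.36, and Cyp51 and Mvd 1.27 each. Hmgcs1 was at 0.69 and Srebf2, the transcription factor that drives the pathway, at 0.46, while Ggps1 (0.11) lay within the probe error. Stard4 was at 0.016 by its brightest probe set and at 0.25 and 0.52 by its others.

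Of 19 genes of fatty acid synthesis, 6 were at least 1.5-fold higher and none of these 19 was 1.5-fold lower, with a median of 0.24 against a random range of -0.19 to 0.15. Apart from Scd1 and Scd2, the members at least 1.5-fold higher were Me1 (0.93), Elovl6 (0.87), Elovl1 (0.70) and Acsl3 (0.65), although the other probe set of Me1 gave 0.083, whereas Fasn was at 0.48 and Srebf1 at 0.25. The 28 genes of phospholipid remodelling and synthesis had a median of 0.11, at the upper edge of the random range of -0.16 to 0.11 and just above it after quantile normalisation (0.14, upper limit 0.13), and 23 of them lay within 1.5-fold. Mboat1, the choline kinase gene Chka (0.94) and Agpat2 (0.88) were higher, and Lpcat3 and Pla2g4a (-0.70) lower. Liver X receptor targets had a median of -0.30 over 10 genes, also within the random range of -0.35 to 0.19. That list holds Lpcat3 itself, without which its median was -0.17. The median was -0.042 with the floor at the 70th percentile, and -0.42 without _s_at and _x_at probe sets, below its random range there (lower limit -0.39). Mylip was at -0.84 and Abcg1 was at least 1.75-fold lower, while Scd1 was the 1 member at least 1.5-fold higher. PPAR targets and genes of fatty acid oxidation had a median of 0.094 over 18 genes, within the random range, with Acadl at 1.27, Pparg at 0.98 and Pdk4 at -0.93.

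Intestinal stem cell genes were lower in the knockout pool. Of 28 measured, 26 were lower, 11 by at least 1.5-fold, and the median was -0.44 (1.36-fold lower) against a random range of -0.18 to 0.10. Lgr5, a receptor that marks crypt base columnar stem cells, was 4.75-fold lower (814 against 171) by its 1 probe set above the floor. Nrn1 was at -1.83, Slc12a2 at -1.09, Cdk6 at -1.05 and Sox9 at -0.99. Axin2 was at -0.76 and Smoc2 at -0.54, and Ascl2 was at -0.56 by its brightest probe set and at -0.90 and -1.06 by its others. Olfm4 was at -0.59, with signals above 20000 on both arrays (32027 against 21348). Tert (0.022) lay within the probe error, as did Lrig1 (-0.0081) and Igfbp4 (0.10) by their brightest probe sets, but others of these genes reached -0.45 and -0.47. Wnt targets and pathway genes, which share members with the stem cell list, had a median of -0.36 over 19 genes (random range -0.21 to 0.12), with 7 at least 1.5-fold lower. Of these 7, Lgr5, Sox9, Rnf43, Axin2 and Ephb3 are also stem cell list members and Mmp7 is a Paneth list member, which leaves Sp5 (-0.73). The Wnt median is therefore not a result separate from that of the stem cell list. Myc was at -0.29, Ctnnb1 at -0.049, Ccnd1 at 0.20 and Tcf7l2 at 0.26. Proliferation genes had a median of -0.23 over 34 genes (random range -0.12 to 0.11), and 32 of them lay within 1.5-fold. Mcm6 (-0.72) and Ccna2 (-0.59) were the members at least 1.5-fold lower, though their second probe sets gave only -0.34 and -0.16, Mki67 was at -0.29 and Birc5 at 0.26. In the same pools the T and natural killer genes of the immune list were lower by a median of -2.10.

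**Figure D2:**
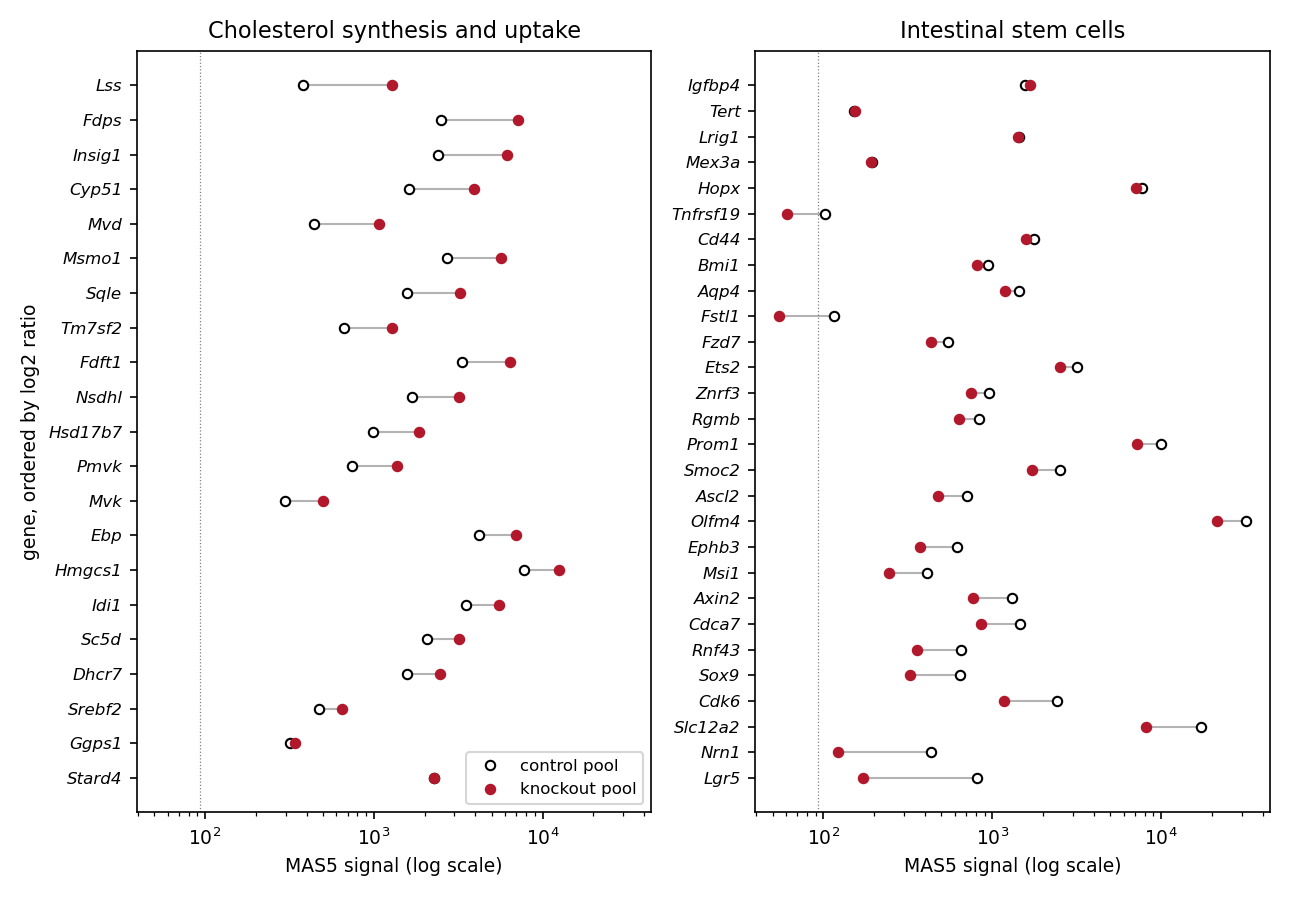
MAS5 signal (x axis, log scale) of each measured gene of the cholesterol synthesis list (left) and the intestinal stem cell list (right), 1 array per pool, ordered by log2 ratio; open points are the control pool, red points the knockout pool and the dotted line the floor. All 21 cholesterol genes are higher and 26 of 28 stem cell genes are lower in the knockout pool.

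Markers of Paneth cells, which lie between the stem cells at the crypt base, had a median of -0.55 over 10 genes (random range -0.23 to 0.20), 5 of them at least 1.5-fold lower. The list holds 27 genes, but none of its alpha-defensin genes was among the 10 measured. Mptx1 was at -1.90, Itln1 at -1.18, Pnliprp2 at -1.12, Ang4 at -1.02 and Mmp7 at -0.71, whereas the lysozyme gene Lyz1 was at -0.27 (46003 against 38133). Signals of Itln1, Ang4 and Lyz1 exceeded 20000 on at least 1 array. Without such members the Paneth median was -0.38, only just below the range of its own random lists (-0.37 to 0.25). Tuft cell markers had a median of -0.89 over 9 genes (random range -0.39 to 0.21), with Rgs13 at -1.28, Ltc4s at -1.18 and Dclk1 at -1.13. Enteroendocrine markers had a median of -0.58 over 20 genes (random range -0.25 to 0.13), 10 of them at least 1.5-fold lower. Among these hormone-cell genes Ghrl (-1.09), Sst (-1.08) and Isl1 (-1.04, and -0.11 by its other probe set) were lowest, and Sct (0.60), Nts (0.52) and Pyy (0.31) were highest. Goblet cell markers lay just below their random range (median -0.15 over 17 genes, range -0.14 to 0.17), 15 of them within 1.5-fold, with Ccl6 at -1.62, Tpsg1 at -0.60, and Atoh1 and Retnlb highest at 0.35 each. Without members above 20000 the goblet median was -0.10, within the range of its own random lists (-0.21 to 0.18).

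Absorptive enterocyte genes went both ways. Of 28, 5 were at least 1.5-fold higher and 5 at least 1.5-fold lower, and the median of 0.12 was within the random range. The retinol-binding protein gene Rbp2 was at 1.20, Dgat2 at 0.84 and Mttp, which loads lipid onto lipoproteins, at 0.66. Cyp2b10, Cd36 and the lactase gene Lct (-1.36) were lowest. Without members brighter than 20000 on either array the enterocyte median was -0.067. Part of that fall is built in, since Mttp was left out for a signal above 20000 in the knockout pool only. After quantile normalisation the enterocyte median was 0.11, just above its random range there (upper limit 0.105). Proximal small-intestinal genes had a median of -0.52 over 14 genes (random range -0.15 to 0.19), with Ces1d, Cyp2b10 and Cubn (at least 4.45-fold lower) lowest and Mt1 highest at 0.99. Distal small-intestinal genes had a median of -0.079 over 10 genes, within the random range, with Cubn, Ceacam20 (-0.76) and Osr2 (at least 1.62-fold lower) lowest and Slc7a9 (0.40), Slc51a (0.37) and Slc51b (0.35) highest.

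Immune cell genes went both ways. Over 19 genes the median was -0.66 (random range -0.22 to 0.12), with 10 at least 1.5-fold lower and 5 at least 1.5-fold higher. Divided after the values were seen, all 8 T and natural killer genes were at least 1.5-fold lower (median -2.10), while all 5 B and plasma cell genes were higher (median 1.14), and of the other 6 genes 3 were higher and 3 lower (median -0.11). Second lists of other genes of these cells, written after the values above were seen, gave smaller medians, -0.72 over 19 T and natural killer genes (18 lower) and 0.30 over 13 B and plasma cell genes (10 higher). Ighm, the immunoglobulin M heavy chain gene, was at 1.95 by its brightest probe set but at 1.32 and 0.072 by others above the floor. Jchain, which joins secreted antibodies, was at 2.33. Genes of MHC class II and antigen presentation had a median of -0.77 over 13 genes (random range -0.18 to 0.19), 7 at least 1.5-fold lower, with H2-Ab1 at -1.60, Cd74 at -1.48 and H2-Aa at -1.23. The class I genes H2-K1 (-0.12) and H2-D1 (-0.069) and the peptide transporter gene Tap1 (0.088) lay within the probe error, with probe sets of both class I genes going both ways. Interferon response genes had a median of 0.36 over 16 genes (random range -0.27 to 0.14), 6 at least 1.5-fold higher, among them Rsad2 (1.27), Usp18 (1.10) and Mx1 (at least 2.47-fold higher), with Irf1 at -0.52. Stromal, muscle and vessel genes (5 measured, median 0.32) were within their random range. So were the 3 measured genes of the blood and exocrine pancreas list (median 0.25), but no blood gene was among them. These 3 were the pancreatic-type elastase gene Cela1 (1.11), Prss2 (at least 1.19-fold higher) and Cela3b (0.11).

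The unfolded protein and integrated stress response list had a median of 0.34 over 21 genes (random range -0.14 to 0.16), 5 at least 1.5-fold higher and 16 within 1.5-fold, led by Chac1 (1.14), Atf3 (0.95) and Creld2 (0.88). Immediate early and heat shock genes had a median of 0.24 over 18 genes (random range -0.20 to 0.13), 5 at least 1.5-fold higher and 13 within 1.5-fold. Hspa1b was at 3.59 and Hspa1a at least 4.08-fold higher, while Ier2 (-0.36), Egr1 (-0.23) and Nr4a1 (at least 1.08-fold lower) were lowest. Antimicrobial and mucosal defence genes had a median of 0.26 over 9 genes (random range -0.27 to 0.23), in which the lectin genes Reg3g (0.95) and Reg3a (-1.03) went opposite ways. Its median was 0.17 after lowess and 0.20 without members above 20000, both within their own random ranges (up to 0.22 and 0.27). The p53 targets had a median of 0.11 over 14 genes, within the random range, with Cdkn1a at 0.64 and Trp53inp1 at -1.07. The 9 housekeeping genes measured, of 12 on the list, had a median of 0.088, and none of the 9 differed by 1.5-fold. The array's control probe sets for Gapdh and Actb, which enter no list, were higher in the knockout pool. Those for Gapdh were at 0.36 to 0.55 and those for Actb at 0.11 to 0.39.

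Of the 25 gene lists, 6 had a median above and 10 below the central 95% of random lists. By chance 1.25 would be expected outside if the genes within a list varied independently, which co-regulated genes do not. Lists with shared members are also not separate results. Of the 16 lists outside, all but the goblet and antimicrobial lists kept their side of the random range when it was recomputed under each alternative setting for scaling, floor, probe sets and bright members. The margin was narrow for Paneth genes without members above 20000 (-0.38, lower limit -0.37). It was also narrow for immune genes with the pseudocount (-0.18, lower limit -0.17). The counts depend on the floor: with it at the 30th percentile 422 genes were at least 2-fold higher and 631 lower, and at the 70th percentile 79 and 97. A pseudocount equal to the floor, used in place of it, shrinks ratios of dim genes and takes in genes below the floor on both arrays. With it, medians moved to -0.32 for Paneth, -0.29 for tuft, -0.38 for enteroendocrine, -0.24 for Wnt and -0.18 for immune genes, and that of stromal genes to -0.034.

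**Figure D3:**
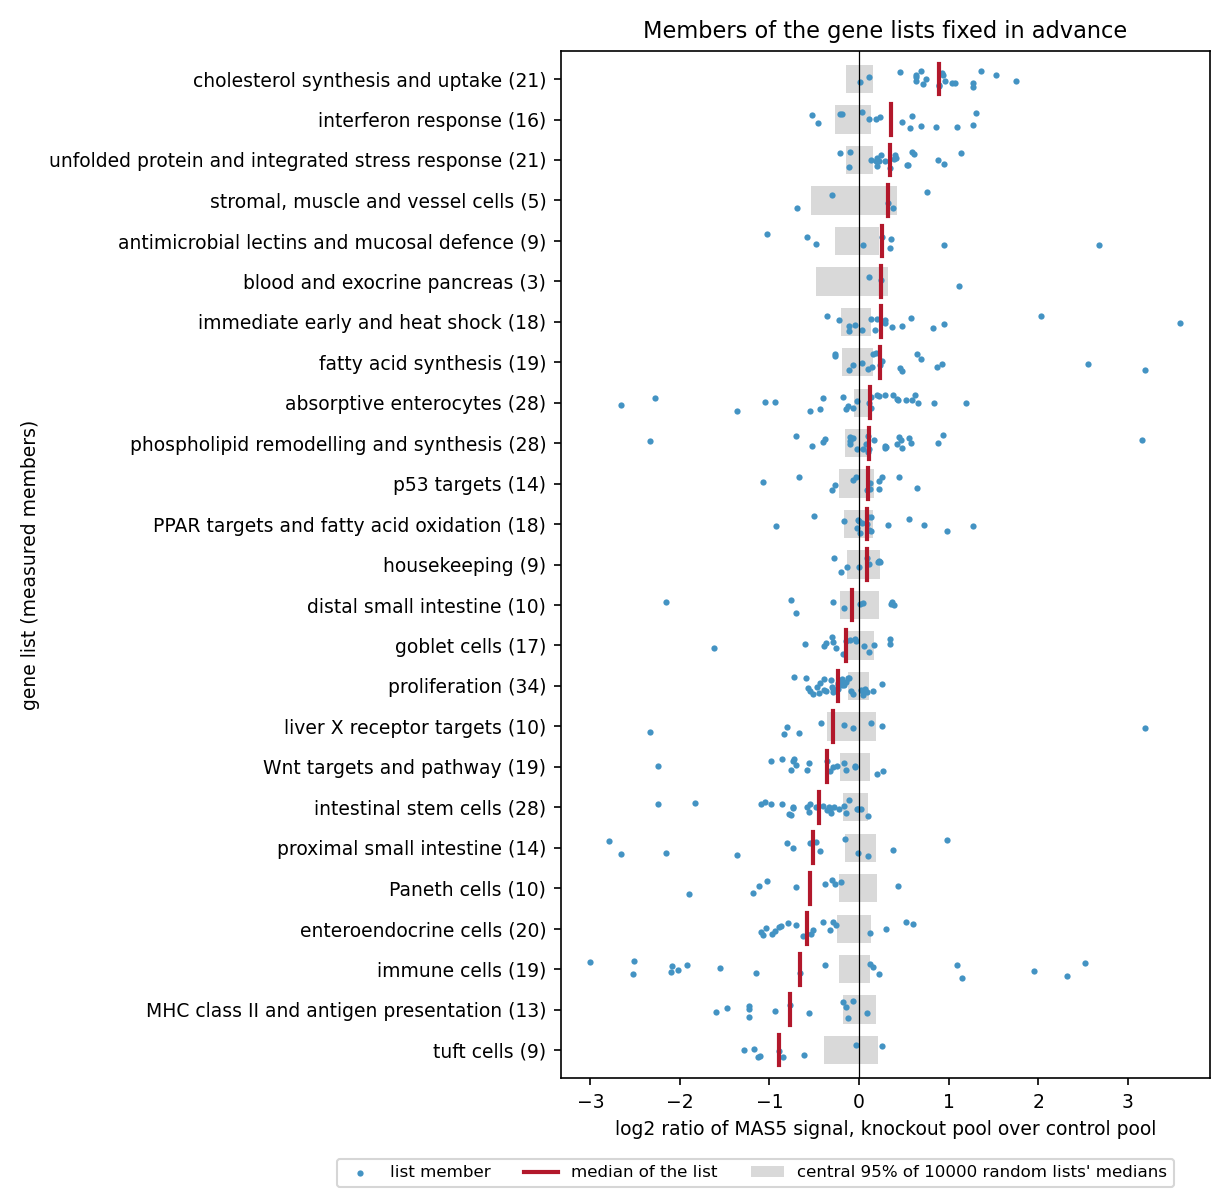
Log2 ratio of MAS5 signal, knockout pool over control pool (x axis), for the measured members of each of the 25 gene lists (y axis, number of members in parentheses); blue points are genes, with genes below the floor on 1 array drawn at their bound, red bars are list medians and grey bars the central 95% of medians of 10000 random lists. The cholesterol list has a median of 0.90 and the tuft cell list one of -0.89.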

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

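The 3 control probe sets for 18S ribosomal RNA, which enter no comparison, had a median log2 ratio of 0.63 (0.56 to 0.89), higher in the knockout pool, while the hybridisation controls had a median of 0.027. Among the 10092 probe sets with no gene name or several, of which 3734 were above the floor on at least 1 array, 40 were at least 2-fold higher and 60 at least 2-fold lower in the knockout pool.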

How the results depend on the processing

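No paired analysis was possible because each group is 1 array, and for the same reason no array could be left out. The median of cholesterol genes stayed between 0.84 and 0.96 and that of fatty acid genes between 0.19 and 0.30 under the 8 planned settings for scaling, floor and probe sets. Over those settings, 172 of 197 list medians moved by less than their probe error, 25 moved by more, and no list outside its random range turned its sign. With random ranges recomputed under each setting, which was decided after seeing the data, 14 of 16 lists outside their range stayed outside on the same side. Paneth genes without members over 20000 and immune genes with the pseudocount did so only narrowly. Goblet genes came within it after quantile normalisation (-0.15), with the floor at the 30th percentile (-0.15) and without members over 20000 (-0.10), and antimicrobial genes after lowess (0.17) and without members over 20000 (0.20). Some lists within their range came just outside it: liver X receptor genes without _s_at and _x_at probe sets (-0.42), enterocyte genes after quantile normalisation (0.11), and phospholipid genes after quantile normalisation (0.14) and with the pseudocount (0.11). For the 268 named genes, 1977 of 2094 ratios moved by less than 1 SD of probe error and no gene at least 2-fold higher or lower turned its sign. Of the 429 genes at least 2-fold higher or lower, 379 kept that call with medians set equal, 375 after quantile normalisation, 376 after lowess, 429 with the floor at the 30th percentile, 176 at the 70th percentile, 216 with the pseudocount, 348 with the median over probe sets and 402 without _s_at and _x_at probe sets. The cause of a shift was not tested unless the setting's construction gives it.

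A floor at the 30th percentile measures more genes and gave 422 genes higher and 631 lower at 2-fold, with medians of -0.34 for Paneth, 0.48 for interferon, -0.55 for stem cell, -0.14 for stromal and -0.73 for tuft genes. At the 70th percentile there were 79 and 97 genes, and medians of -0.71 for Paneth, -0.46 for Wnt, -0.70 for enteroendocrine, -0.81 for immune and -0.042 for liver X receptor genes. The pseudocount, which shrinks ratios of dim genes, gave 129 genes lower and medians of -0.54 for MHC class II, -0.32 for Paneth, -0.24 for Wnt, -0.38 for enteroendocrine, -0.18 for immune, 0.25 for interferon, -0.034 for stromal and -0.29 for tuft genes. At 3-fold there were 43 genes higher and 54 lower, and at 1.5-fold 547 and 1005. Equal medians gave -0.17 for proliferation genes. The median over probe sets gave -0.56 for MHC class II, -0.54 for stem cell and -0.36 for proximal genes. Without _s_at and _x_at probe sets the medians were -0.71 for Paneth, -0.42 for liver X receptor and 0.0071 for stromal genes. Settings chosen after seeing the data gave -0.17 for liver X receptor genes without Lpcat3. Without members over 20000 they gave -0.38 for Paneth, -0.46 for Wnt, -0.067 for enterocyte and -0.52 for immune genes. This setting drops a member above 20000 on either array, so a difference between the pools can decide which members stay. Mttp and Reg3g were above 20000 only in the knockout pool, and Itln1 and Ang4 only in the control pool. The split of the immune list gave -2.10 for T and natural killer genes and the opposite sign, 1.14, for B and plasma cell genes. The SD of probe error was 0.354 with the floor at the 30th and 0.220 at the 70th percentile, so dim signals limit the precision.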

Other observations

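The tests of the enterocyte share and both tests of crypt base cells were chosen only after the result was seen, and the fetal-like, NRF2, drug metabolism and second lymphocyte lists were written after the first gene values had been seen. Sprr1a, Anxa10, Tnfrsf12a, S100a6 and Il33 were among the highest genes, and a hypothesis is that a fetal-like or regenerating epithelial programme may be higher in the knockout pool. A list of 15 measured genes of that programme, without those genes, had a median log2 ratio of 0.36 against a random range of -0.30 to 0.19. Of these, 7 were at least 1.5-fold higher and 1 at least 1.5-fold lower. Anxa3 (1.32), Plaur (1.17), Cldn4 (0.88), Emp1 (0.85) and Clu (0.82), examples chosen after their values were seen, were higher.

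Akr1b8 and Gsta3, also among the highest, led to the hypothesis that targets of NRF2, the transcription factor of the oxidative stress response, may be higher. The other 18 measured targets had a median of 0.34 (random range -0.10 to 0.17), 5 at least 1.5-fold higher and 1 at least 1.5-fold lower. Examples chosen after their values were seen are Cbr3 (1.34), Pgd (0.76), Srxn1 (0.75) and Gclc (0.69). Cyp2c29, Ces1d and Cyp2b10 were among the lowest genes, and lower activity of the drug metabolism receptors CAR and PXR was tested on a list of 23 other genes. Its median was -0.057, inside its random range of -0.10 to 0.16, with 10 members higher and 13 lower. The limit set before the test took a median within that range as the outcome against the hypothesis, and these 23 genes showed no common lowering. Because the list leaves out Cyp2c29, Ces1d and Cyp2b10, the question stays open for those 3 genes.

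Cholesterol synthesis genes were higher in the knockout pool. Scaling or an intensity trend does not account for this, since the median was at least 0.91 after quantile normalisation and lowess, nor does error of single probe sets, since second probe sets of 12 of the genes had a median of 0.83 and 11 were higher. A larger share of enterocytes is argued against, but only weakly, by 23 enterocyte markers below 20000 in the control pool. Their upper quartile was 0.48 and their median 0.13, under the cholesterol median of 0.90. These markers ran from -2.65 (Cyp2b10) to 1.20 (Rbp2). A common change in cell share would not give that spread, so they measure the share only roughly. The 21 markers at or below 20000 on both arrays had a median of -0.067. That set leaves out Mttp because its signal passed 20000 in the knockout pool, so this lower median adds no evidence. The loss of Lpcat3, effects of Cre and differences between the pools of mice stay open and untested.

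Stem cell genes were lower in the knockout pool. The median was -0.43 or lower after quantile normalisation and lowess, which argues against scaling as the cause. Fewer crypt base cells in the knockout pool remain a possible explanation for the list as a whole. Paneth cell genes were lower by a similar amount (Paneth median minus stem cell median -0.10). This match does not single out the crypt base. Tuft (-0.89) and enteroendocrine (-0.58) markers were lower still, though goblet (-0.15) and enterocyte (0.12) markers were not. The Paneth median also holds no alpha-defensin gene and ran from -0.71 to -0.32 over the settings. Whether fewer crypt base cells account for the size of the Lgr5 ratio stays open. The lowest of Ascl2, Smoc2, Axin2 and Olfm4 lay 1.49 above that ratio, past the limit set as the outcome against this explanation. However, Nrn1 of the same list, which was not among the genes chosen for that test, lay only 0.41 above it. Lgr5 rests on 1 probe set above the floor. How the crypts were isolated in each pool, Cre and genotype stay open and untested.

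T and natural killer genes were lower and B and plasma cell genes higher in the knockout pool. A lower share of all immune cells would put B and plasma cell genes below 0, and a second list of 13 such genes had a median of 0.30 (10 of 13 higher; 5 of the 13 were bounds), above its random range of -0.33 to 0.15. This argues against it as the whole cause, while the limit first set for the test, 1 SD of probe error (0.28), was the error of single genes and not suited to a list's median, which passed it narrowly. Fewer T and natural killer lymphocytes cannot be told apart from lower expression within them, because RNA of a whole pool does not show the amount per cell. No median of a gene list could have decided this. The second list of 19 T and natural killer genes had a median of -0.72, between the limits set for the test, and 8 of the 19 were bounds. Genotype, Cre and pool stay open and untested.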
